A study of Homo sapiens with 6 samples.

How the data were processed

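RNA was measured in 6 samples of the A172 glioblastoma cell line, 3 kept for 5 days with DMSO and 3 with 20 nM MRTX1719. Per the labels' protocols, the cells grew in DMEM with fetal bovine serum, RNA was extracted from frozen cells with a Qiagen RNeasy kit, and libraries were made with an ABclonal kit after poly(A) selection. The samples were grouped by the treatment and replicate number that their titles give.

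The authors deposited 1 table of raw read counts per Ensembl gene, 1 column per sample, without normalization or pooling. The submitters' processing notes name HISAT2, an aligner, featureCounts, which counts reads per gene, and the hg38 and GRCh38 builds. Their versions, the annotation release, the strand setting of the counting and the treatment of reads that fit several places are not given in the sources used here. Reads from overlapping genes on opposite strands and from near-identical copies therefore cannot be assigned with certainty. Poly(A) selection keeps few reads of RNAs without a tail, such as most histone mRNAs. The table holds 58735 gene IDs, and all 58735 occur in GENCODE release 29 for GRCh38, from which positions, gene types, exon lengths and GC content were taken. Current symbols matched 58207 IDs, and the remaining 528 kept their name in that release. Of all IDs, 25490 had no count in any library.

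Library totals ran from 39544272 to 49123919 counted reads, so that 3 counts equal 0.0611 to 0.0759 CPM. Between 26135 and 27104 genes had a count in a library, and the 10 genes with the most counts took 6.18% to 6.32%. Log2 CPM of libraries of one group correlated at 0.9963 to 0.9979 (Pearson, across genes, which are not independent replicates), and libraries of different groups at 0.967 to 0.9705. A chi-square statistic per gene was 3.29 to 6.46 between libraries of one group, above the value of 1 that sampling noise alone gives, so no library appeared to have been deposited a second time. The labels give no batch or sequencing date.

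Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 18152 genes, 13928 of them protein-coding. Libraries were scaled by TMM, and the robust quasi-likelihood F test compared MRTX1719 with DMSO, with no covariate and two-sided p-values adjusted by the Benjamini-Hochberg method. The standard error of a log2 fold change was its size divided by the square root of F. The common biological coefficient of variation was 0.0495. CPM values use the TMM-scaled library sizes.

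A set of 39 gene lists was fixed before the data were examined. They were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move, on balance, one way, without comparing them with other genes. Of the 39 lists, 19 passed with the preset correlation and 29 with fry. With the estimated correlation 0 passed at an adjusted p of 0.05, and 8 had an unadjusted p under 0.05. In each list, genes were also adjusted over the list alone.

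Named genes followed a rule fixed before the data were examined. It took the 10 largest rises and 10 largest falls among genes past a false discovery rate of 0.05 with a mean of at least 5 CPM and groups that do not overlap, the 5 smallest p, and in each list that passed up to 4 genes with the smallest p in the direction of the list. PRMT5, WDR77, CLNS1A, RIOK1, COPRS, MTAP, CDKN2A, CDKN2B, CDKN1A, MDM2, MDM4, MAT2A, E2F1, MKI67, GFAP and SOX2 were always named. A few genes that the rule takes are not reported here. Sex-linked marker genes were left out. APAF1, IGFBP3, PRMT3, NDUFAF7, CCND1, CDK6, H2AC20, H1-5, DDX20, GEMIN4, GEMIN6, GEMIN8, KLHL9, DMRTA1, LIF and TRIM22 were named after their values were seen.

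The alternatives fixed in advance were DESeq2 1.42.0, limma-voom, other library scalings, no expression filter or at least 1 CPM in at least 3 libraries, a false discovery rate of 0.01, mitochondrial genes left out, the replicate number as a block and each library left out in turn. Removal of a loess trend (span 0.3) of each library on GC content and exon length, and thinning to the smallest library, were added after the data had been seen. The gene test was tested on counts simulated for this comparison over 17846 genes. It recovered 42% of 50 genes changed 1.2-fold, 66% of 50 changed 1.5-fold, 84% of 50 changed 2-fold and 98% of 50 changed 4-fold, and called 14 of 17648 unchanged genes. Of the changed genes, 2 fell below the filter and count as not recovered. Far fewer genes were changed than passed in the real data, so the adjusted threshold was stricter and these rates do not carry over to the real test. In a simulation of 17860 genes with 1 of the 39 lists shifted by 0.5 log2 units, each of the 3 list tests found that list and camera with the preset correlation called 0 others. These counts were drawn independently per gene and hold no correlation within lists, whereas on the real libraries estimated correlations reached 0.682. The simulation therefore gives no rate of false lists for these data. The other 9 splits of the 6 libraries into 3 and 3, which mix the treatments, gave 9 to 17 lists with 0 genes called. Each sets 2 libraries of one treatment and 1 of the other against the reverse. Part of the treatment difference remains in them, so they give no such rate either. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and Matplotlib 3.10.9.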

Results

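A172 is an established human glioblastoma cell line. The cells were grown for 5 days with 20 nM MRTX1719 or with DMSO, the solvent control. MRTX1719 inhibits PRMT5, an enzyme that places symmetric dimethyl marks on arginine residues of spliceosomal, histone and other proteins. The compound binds PRMT5 together with methylthioadenosine, a metabolite that accumulates in cells lacking the salvage enzyme MTAP. Poly(A) RNA was sequenced from 3 libraries per group, and the series poses the question of which transcripts differ after PRMT5 inhibition. The DMSO libraries held 41402737, 39544272 and 44827212 counted reads, and the MRTX1719 libraries held 43756645, 42660419 and 49123919. The series describes the 3 samples of a group as biological samples without saying whether they came from separate cultures, so the p-values measure the spread between these samples only. All fold changes are MRTX1719 over DMSO, levels are CPM, read counts scaled to a common library size, as mean ± SD with n = 3 per group, and positions are on GRCh38.

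After 5 days of MRTX1719 the cells held a larger share of RNA of p53 target genes, of ATF4 targets and of those secreted inflammatory factors that could be tested. They held a smaller share of RNA of the genes for mitosis, DNA replication and cholesterol synthesis. These 6 lists passed camera with a preset correlation and none passed with an estimated one, where their adjusted p was 0.0747 to 0.324. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 4.12-fold from 218 ± 7.2 to 897 ± 23 CPM. MKI67, the gene of the proliferation marker Ki-67, fell from 148 ± 9.9 to 49.1 ± 3.9 CPM. Of 18152 genes tested, 9083 passed a false discovery rate of 0.05 in edgeR's quasi-likelihood test, 4495 higher and 4588 lower. Most of these changes were small. Only 1298 of the called genes changed at least 2-fold, 813 upward and 485 downward, and the median absolute log2 fold change of the called genes was 0.40. The 3 libraries of one group lay entirely above or below those of the other for 10273 genes, 56.6% of those tested, where chance gives 10%. The first principal component separated the groups and held 64.9% of the variance. With only the genes of at least 1 CPM in at least 3 libraries kept, the number changed at least 2-fold was 765.

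**Figure D1:**
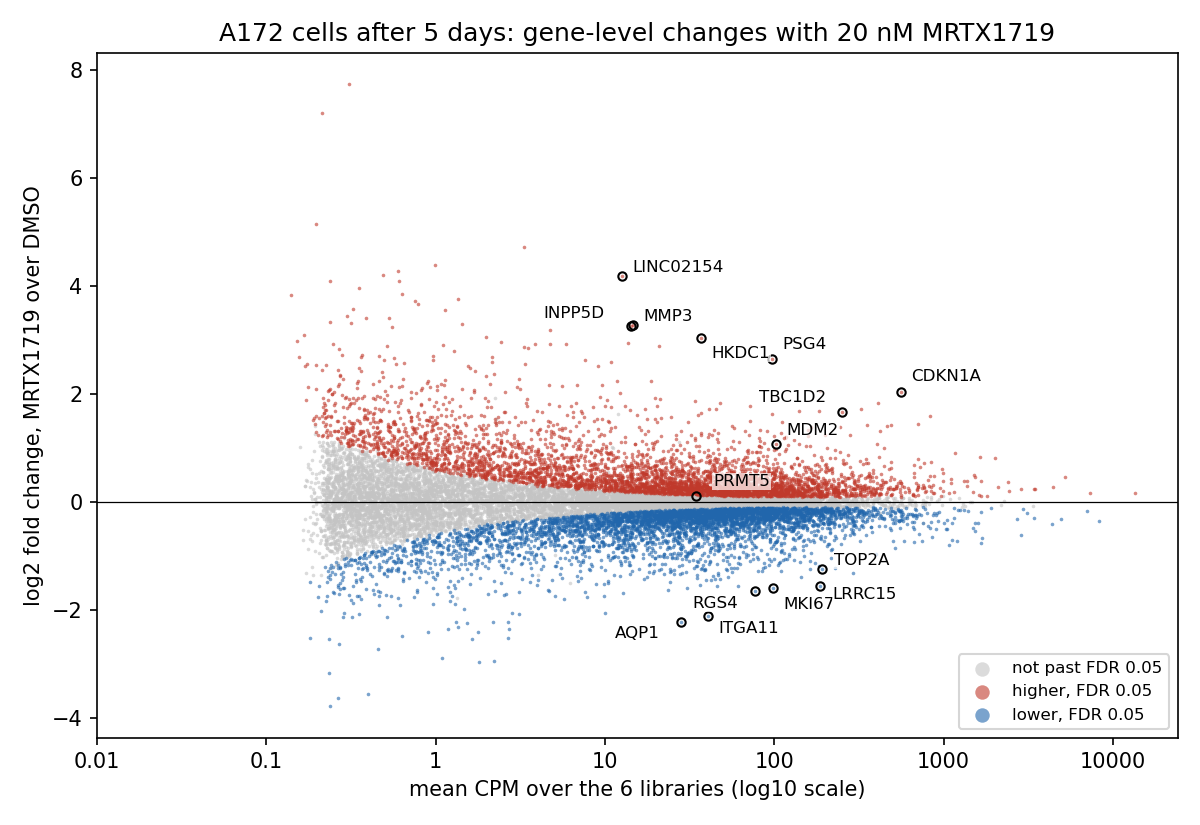
Each point is 1 tested gene, with its mean CPM over the 6 libraries on a log10 scale on the x axis and its log2 fold change of MRTX1719 over DMSO on the y axis; red and blue points passed a false discovery rate of 0.05. CDKN1A lies at a log2 fold change of 2.04 and AQP1 at -2.22, and most coloured points lie within 1 log2 unit of the zero line.

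Among genes with a mean of at least 5 CPM, LINC02154, MMP3 and INPP5D rose most. LINC02154, a long non-coding RNA gene (ENSG00000235385, chromosome X, 13266048 to 13303452), rose from 1.33 ± 0.35 to 23.9 ± 2.2 CPM, an 18.1-fold change (log2 fold change 4.18, SE 0.12, adjusted p = 1.76e-20). MMP3, which encodes the matrix protease stromelysin-1, rose 9.68-fold. INPP5D, the gene of the inositol phosphatase SHIP1, rose 9.6-fold, and HKDC1, a hexokinase family gene, rose 8.26-fold to 66.2 ± 4.5 CPM. GRIN2C (an NMDA receptor subunit) rose 7.72-fold, the tetraspanin gene TSPAN8 7.63-fold, the acetylcholinesterase gene ACHE 7.43-fold, and PCP4 6.23-fold. PSG4, a pregnancy-specific glycoprotein gene (ENSG00000243137, chromosome 19, 43192702 to 43207299), rose 6.25-fold from 26.6 ± 1.2 to 166 ± 4.4 CPM and had the smallest p of all genes (adjusted p = 1.77e-27). It belongs to a family of near-identical copies, so the share of its reads that came from other members is uncertain. LIF-AS2 rose 6.07-fold from 3.06 ± 0.16 to 18.6 ± 0.77 CPM. It lies antisense to LIF, which rose 1.28-fold from 104 ± 3.9 to 133 ± 2.9 CPM, and without a stated strand setting the share of its reads that came from LIF is uncertain. TBC1D2, a Rab GTPase-activating protein gene, rose 3.16-fold to 383 ± 9.6 CPM and was among the 5 genes with the smallest p.

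AQP1 and ITGA11 had the largest falls under the same rule. AQP1, the water channel gene (ENSG00000240583, chromosome 7, 30911694 to 30925516), fell from 46.5 ± 2.2 to 9.98 ± 0.92 CPM (log2 fold change -2.22, SE 0.067, adjusted p = 5.44e-22). The collagen-binding integrin gene ITGA11 fell from 65.8 ± 5.2 to 15.2 ± 1.9 CPM. LRRC15, which encodes a leucine-rich repeat membrane protein, fell from 278 ± 4.8 to 94.6 ± 1.2 CPM, and RGS4, a regulator of G protein signalling, from 117 ± 6.1 to 37.2 ± 3.3 CPM. The co-repressor gene TLE2 (log2 fold change -2.05), DNM3OS (-1.81), SERPINF1 (-1.76), FXYD6 (-1.74), BST2 (-1.68) and the centromere protein gene CENPI (-1.66) were also among the 10 largest falls, as was RGS4. DNM3OS hosts microRNA genes and AQP1 and FXYD6 overlap a further annotated gene on the same strand, so some of their reads are not attributable to one gene. The falls named here had an adjusted p of at most 1.62e-12.

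PRMT5 RNA itself showed no detected difference, at 33.4 ± 0.4 CPM in DMSO and 35.8 ± 0.78 CPM in MRTX1719 (log2 fold change 0.10, SE 0.053, adjusted p = 0.112). Its partner WDR77 (log2 fold change 0.06) and the adaptor CLNS1A (0.07) did not pass either, although CLNS1A passed with the GC and length trend removed (0.15, adjusted p = 0.00403). COPRS, an adaptor that brings PRMT5 to histones, rose by 0.35 on the log2 scale. RIOK1, another PRMT5 adaptor, rose by 0.20 (adjusted p = 0.0291), a call that was lost without DMSO replicate 1 (0.0744), DMSO replicate 2 (0.0705), MRTX1719 replicate 1 (0.0845), MRTX1719 replicate 2 (0.0518) or MRTX1719 replicate 3 (0.0538). As a list these 5 genes did not pass camera with a preset correlation (adjusted p = 0.0856; adjusted p = 0.324 with an estimated correlation), but passed with fry (0.00106). Of 8 other arginine methyltransferase genes, PRMT3 rose, NDUFAF7 fell and 6 did not pass (adjusted p = 0.654). Of 16 genes of methionine salvage and polyamine synthesis, 4 rose, 3 fell and 9 did not pass (adjusted p = 0.603), and MAT2A, which makes S-adenosylmethionine, was among the last at a log2 fold change of -0.06. For each of these lists the counts adjusted over the list alone were the same.

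MTAP, on chromosome 9 from 21802543 to 21937651, had 3, 0 and 5 reads in the DMSO libraries and 11, 12 and 5 in the MRTX1719 libraries, too few to be tested. CDKN2B had 0 to 3 reads per library. CDKN2A, the neighbouring gene of p16 and p14ARF, had 7 to 42 reads per library and a log2 fold change of 1.48 (SE 0.40, adjusted p = 0.00272). It lay near the floor, at 0.24 ± 0.088 CPM in DMSO and 0.67 ± 0.30 CPM in MRTX1719, beside genes with almost no reads. Whether these few reads came from CDKN2A transcripts is uncertain, so the change is no evidence of induction. KLHL9, farther along the same chromosome arm, had 2479 to 3124 reads per library and did not pass. Of the 5 tested genes of this locus 2 were higher, CDKN2A and DMRTA1, and 3 did not pass, also when adjusted over the list alone; the list did not pass (adjusted p = 0.46).

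Genes activated by p53 rose nearly throughout. Of 33 measured p53 targets 32 rose and 1, APAF1, fell, both over all genes and adjusted over the list alone, with a median log2 fold change of 0.91 (camera adjusted p = 1.33e-16; adjusted p = 0.0747 with an estimated correlation). Beside CDKN1A, the antiproliferative gene BTG2 rose 3.65-fold, the RNA-binding protein gene ZMAT3 2.52-fold and the DNA damage recognition gene DDB2 2.28-fold. MDM2, the ubiquitin ligase gene that p53 induces and that limits p53, rose 2.12-fold from 65.8 ± 2.2 to 139 ± 5.5 CPM (adjusted p = 6.8e-19). MDM4, whose transcript depends on exon inclusion for its protein, had a log2 fold change of -0.07 at the gene level (adjusted p = 0.369), and gene counts do not show exon use.

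Cell cycle genes fell. All 58 measured genes of the G2 and M phases fell, with a median log2 fold change of -1.14, a 2.2-fold lower level (adjusted p = 3.26e-30; adjusted p = 0.167 with an estimated correlation). TOP2A, which untangles replicated chromosomes, fell from 269 ± 2.5 to 113 ± 8 CPM, CDC20 from 154 ± 7 to 63.8 ± 2.3 CPM, ANLN from 257 ± 1.4 to 113 ± 4.9 CPM and the chromokinesin gene KIF4A from 77.6 ± 4.1 to 29.7 ± 0.92 CPM. Of 46 DNA replication genes 42 fell, none rose and 4 did not pass, with a median of -0.61 (adjusted p = 6.49e-17; adjusted p = 0.0747 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell by 1.22 on the log2 scale, the thymidine kinase gene TK1 fell by 1.08, MCM10 fell by 1.04 and TIMELESS fell by 0.82. For both lists the counts adjusted over the list alone were the same.

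Of 22 G1/S and E2F regulators 18 fell, 2 rose and 2 did not pass (19 fell adjusted over the list alone), with a median of -0.53 (adjusted p = 9.3e-06; adjusted p = 0.188 with an estimated correlation). MYBL2 fell from 207 ± 2.4 to 78.8 ± 3.1 CPM, the cyclin A gene CCNA2 from 83.8 ± 3.7 to 35.9 ± 1.2 CPM, E2F1 from 102 ± 2.5 to 66.5 ± 1.6 CPM, UHRF1 by a log2 fold change of -0.68 and CDK2 by -0.69. The 2 that rose were CCND1 and CDK6. Of 41 genes of homologous recombination and the Fanconi anaemia pathway 28 fell, none rose and 13 did not pass (30 fell adjusted over the list alone), with a median of -0.52 (adjusted p = 1.93e-08; adjusted p = 0.138 with an estimated correlation). The polymerase theta gene POLQ had a log2 fold change of -1.26, and FANCA, FANCD2 and FANCI had -1.23, -1.18 and -1.10.

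**Figure D2:**
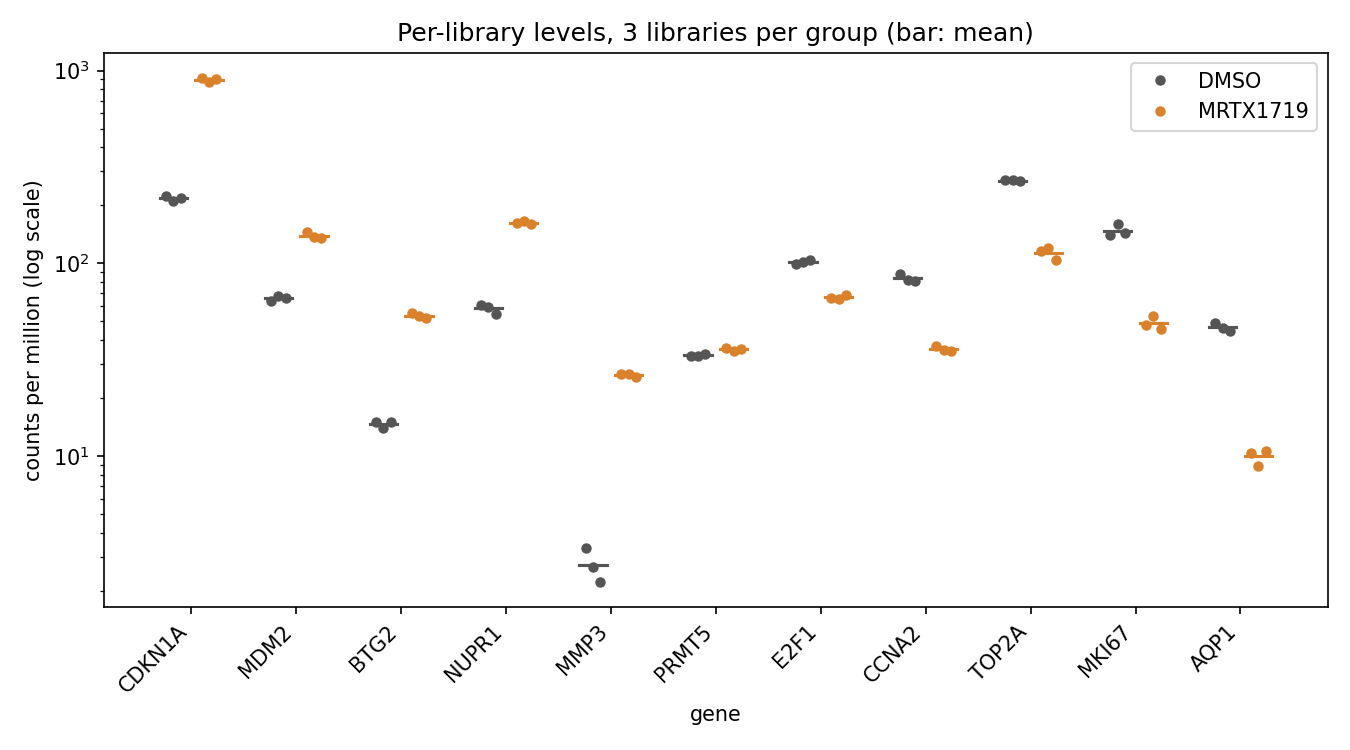
The y axis gives CPM on a log scale for 11 genes named along the x axis; each point is 1 library, grey for DMSO and orange for MRTX1719, and bars are means of 3 libraries. CDKN1A moves from 218 to 897 CPM and MKI67 from 148 to 49.1 CPM, while PRMT5, which did not pass the test, differs by much less.

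Splicing factor RNAs were moderately lower. Of 49 splicing regulators 33 fell, 5 rose and 11 did not pass (35 fell adjusted over the list alone), with a median log2 fold change of -0.25 (adjusted p = 7.52e-06; adjusted p = 0.0747 with an estimated correlation). The largest of these falls were in genes of heterogeneous nuclear ribonucleoproteins, with HNRNPR at -0.87, HNRNPL at -0.61, HNRNPA0 at -0.51 and HNRNPA2B1 at -0.50, the last from 1213 ± 21 to 859 ± 15 CPM. A further list held the Sm and LSm proteins, several of which carry the arginine marks placed by PRMT5, and the SMN complex that assembles Sm proteins. Of its 28 genes 13 fell, among them the SMN complex genes DDX20, GEMIN4, GEMIN6 and GEMIN8, 1 rose and 14 did not pass (14 fell adjusted over the list alone), with a median of -0.16 (adjusted p = 0.0437; adjusted p = 0.557 with an estimated correlation). SNRPD1 had a log2 fold change of -0.33, LSM5 -0.26, LSM7 -0.23 and SNRPB -0.21. LSM7 lies antisense to SPPL2B. The call of this list was lost without DMSO replicate 1 (adjusted p = 0.085), MRTX1719 replicate 1 (0.061) or MRTX1719 replicate 2 (0.0654). Of 45 other core spliceosome genes 18 fell, 7 rose and 20 did not pass, also adjusted over the list alone, and the list did not pass (adjusted p = 0.107); it passed without DMSO replicate 2 (0.0487) and with fry (0.0175).

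Most secreted and inflammatory genes with enough reads to be tested rose. Of 47 listed NF-kB targets and secreted inflammatory factors only 26 were tested. The others, most of them interleukin and chemokine genes, had too few reads. Of the 26, 20 rose, 1 fell and 5 did not pass, also adjusted over the list alone. Their median log2 fold change was 0.73 (camera adjusted p = 1.37e-07, and 0.167 with an estimated correlation). The macrophage growth factor gene CSF1 rose 2.62-fold and the manganese superoxide dismutase gene SOD2 3.28-fold, beside MMP3. SOD2 overlaps other annotated genes on both strands. IGFBP3 fell. Of 49 interferon-stimulated genes 17 rose, 13 fell and 19 did not pass (18 and 14 adjusted over the list alone), and the list did not pass (adjusted p = 0.826), with a median of -0.03 and a test direction of up. BST2, which tethers budding viruses, fell from 19.5 ± 1.5 to 6.1 ± 0.28 CPM, while TRIM22, chosen after its value was seen, rose by a log2 fold change of 1.34. Of 24 antigen presentation genes 12 fell, 3 rose and 9 did not pass (13 and 4 adjusted over the list alone; adjusted p = 0.0603, and 0.0265 without DMSO replicate 2, 0.0424 with limma-voom, 0.0159 without an expression filter and 0.00134 with fry).

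Targets of ATF4, a transcription factor of the integrated stress response, rose while endoplasmic reticulum chaperones fell. Of 34 ATF4 targets 28 rose, 1 fell and 5 did not pass, with a median of 0.45 (adjusted p = 1.93e-09; adjusted p = 0.0747 with an estimated correlation). The stress regulator gene NUPR1 rose 2.78-fold from 58.4 ± 3.2 to 162 ± 2.2 CPM, SESN2, also a p53 target, 2.13-fold, CEBPB 1.8-fold and the tryptophanyl-tRNA synthetase gene WARS1 1.66-fold. Of 22 endoplasmic reticulum chaperone and folding genes 14 fell, 3 rose and 5 did not pass, with a median of -0.27 (adjusted p = 0.00271; adjusted p = 0.321 with an estimated correlation). HSP90B1 fell from 667 ± 16 to 369 ± 4.7 CPM, CALR from 1364 ± 34 to 786 ± 29 CPM, HSPA5 from 1041 ± 42 to 663 ± 8.3 CPM and HYOU1 from 230 ± 4.2 to 149 ± 3.3 CPM. The counts adjusted over the list alone were the same for both lists.

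Sterol and lipid synthesis genes fell. Of 24 cholesterol biosynthesis genes 20 fell, 2 rose and 2 did not pass, with a median of -0.47 (adjusted p = 2.87e-06; adjusted p = 0.324 with an estimated correlation). The fall reached -1.08 in ACAT2, -0.90 in the farnesyl diphosphate synthase gene FDPS, -0.66 in INSIG1 and -0.66 in the squalene synthase gene FDFT1. ACAT2 overlaps annotated genes on the opposite strand, among them a second entry named SOD2. The SOD2 gene whose rise is given above ends at 159745186 on chromosome 6, before ACAT2 starts at 159760328, and does not overlap it. Of 16 fatty acid and lipid synthesis genes 11 fell, 3 rose and 2 did not pass, with a median of -0.32 (adjusted p = 0.00378; adjusted p = 0.321 with an estimated correlation). The elongase gene ELOVL6 had a log2 fold change of -0.83, the desaturase genes FADS1 and FADS2 had -0.72 and -0.54, and the acyl-CoA synthetase gene ACSL3 had -0.55. FADS1 and FADS2 overlap on opposite strands. Lysosome and autophagy genes rose, 24 of 33 against 4 that fell and 5 that did not pass, with a median of 0.30 (adjusted p = 3.11e-05; adjusted p = 0.324 with an estimated correlation). The autophagy receptor gene SQSTM1 rose 1.79-fold to 2111 ± 7.5 CPM, the cathepsin genes CTSB and CTSL 1.76-fold and 1.71-fold, and the cholesterol exporter gene NPC1 1.61-fold. For these 3 lists the counts adjusted over the list alone were the same.

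Of 22 NRF2 targets 16 rose, 2 fell and 4 did not pass (3 fell adjusted over the list alone), with a median of 0.30 (adjusted p = 0.0014; adjusted p = 0.406 with an estimated correlation). The haem oxygenase gene HMOX1 rose 1.93-fold, the ferritin genes FTH1 and FTL 1.66-fold and 1.61-fold, and TXNRD1 1.46-fold. FTH1 and FTL have many processed pseudogenes, so their read assignment is uncertain. Of 33 hypoxia and glycolysis genes 7 rose, 9 fell and 17 did not pass (adjusted p = 0.603). Of 39 MYC and ribosome biogenesis genes 17 rose, 5 fell and 17 did not pass (adjusted p = 0.0689, and 0.0419 without MRTX1719 replicate 2, 0.0439 without an expression filter and 0.0171 with fry). The counts of the last 2 lists were the same adjusted over the list alone.

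Ribosomal protein and respiratory chain RNAs rose by small amounts. Of 78 cytosolic ribosomal protein genes 60 rose, none fell and 18 did not pass (61 rose adjusted over the list alone), with a median fold of 1.15 (adjusted p = 5.2e-09; adjusted p = 0.549 with an estimated correlation). Over all tested genes the log2 fold change declined with exon length, from a median of 0.10 in the shortest 10% of genes to -0.06 in the longest 10%. RPS19 rose 1.55-fold, RPS18 1.39-fold and RPS12 1.28-fold. These genes have many processed pseudogenes, and the authors' treatment of reads that fit several places is not given in the sources used here. Of 47 nuclear-encoded respiratory chain genes 28 rose, 2 fell and 17 did not pass, with a median fold of 1.1 (adjusted p = 0.0015; adjusted p = 0.593 with an estimated correlation). COX4I1 rose 1.22-fold, NDUFV1 1.24-fold, UQCRH 1.21-fold and ATP5PB 1.21-fold. Of 13 mitochondrially encoded genes 11 rose and 2 did not pass, with a median fold of 1.19 (adjusted p = 0.00149; adjusted p = 0.498 with an estimated correlation). MT-ND3 rose 1.73-fold, MT-ND1 1.34-fold, MT-ND2 1.3-fold and MT-ND4 1.22-fold. Mitochondrial genes took 3.38% to 3.76% of the counts in DMSO libraries and 3.83% to 4.04% in MRTX1719 libraries, while mitochondrial ribosomal RNA, a part of these, took 0.78% to 0.89% in DMSO and 0.71% to 0.75% in MRTX1719 libraries. Both respiratory lists had the same counts adjusted over the list alone.

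Of 27 measured replication-dependent histone genes 15 rose, 2 fell and 10 did not pass, also adjusted over the list alone, with a median of 0.44 (adjusted p = 0.00271; adjusted p = 0.406 with an estimated correlation). H3C10 rose from 3.15 ± 0.16 to 7.96 ± 0.79 CPM, H2BC4 from 7.12 ± 0.88 to 13.4 ± 0.79 CPM, H2BC5 from 19 ± 1.4 to 33.7 ± 1.3 CPM and H2AC6 from 34.4 ± 1.9 to 53.7 ± 0.94 CPM. The genes that fell were H2AC20 and H1-5. Most histone mRNAs lack a poly(A) tail and histone genes are near-identical copies, so in poly(A) libraries these values cover only part of the histone RNA and the copy of origin is uncertain. Mitochondrial ribosomal RNA took at most 0.75% of the counts in MRTX1719 libraries and at least 0.78% in DMSO libraries. This share is not a measure of how much RNA without a tail the libraries held.

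**Figure D3:**
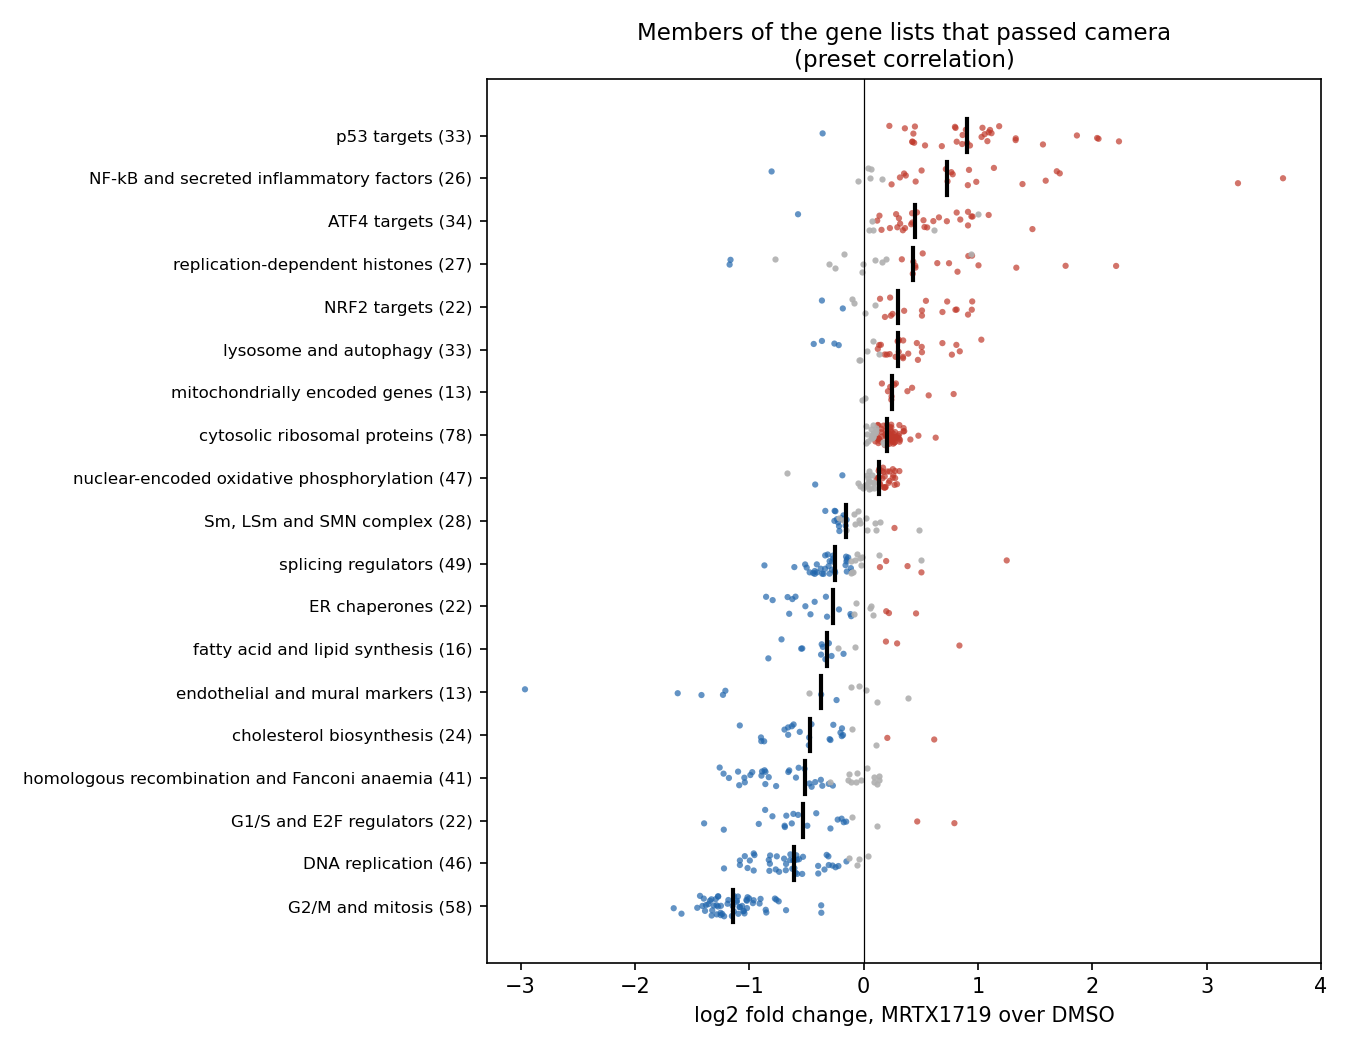
Each point is 1 gene of the 19 lists that passed camera with a preset correlation, its log2 fold change of MRTX1719 over DMSO on the x axis; red and blue points passed a false discovery rate of 0.05, grey points did not, black bars are list medians and the number of tested genes stands beside each list name on the y axis. The medians run from -1.14 for G2/M and mitosis to 0.91 for p53 targets.

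Markers of neural and other cell types moved in both directions. Of 19 neural progenitor and glioma stem markers 5 rose, 9 fell and 5 did not pass (adjusted p = 0.109; 0.00106 with fry). SOX2, a neural stem cell transcription factor, fell from 15.7 ± 1 to 8.83 ± 0.78 CPM. Of 11 astrocyte markers 7 rose, 2 fell and 2 did not pass (3 fell adjusted over the list alone; adjusted p = 0.182, and 0.00136 with fry), and the intermediate filament gene GFAP had 47 to 61 reads per library and a log2 fold change of -0.20 that did not pass (adjusted p = 0.48). Of 14 neuron markers 5 rose and 2 fell (adjusted p = 0.412; 0.00746 with fry), of 5 oligodendrocyte markers 2 fell (adjusted p = 0.567; 0.00945 with fry), of 7 haematopoietic and microglia markers 3 rose (adjusted p = 0.291), and of 13 epithelial markers 4 rose and 5 fell (adjusted p = 0.959). Of 13 endothelial and mural cell markers 7 fell, none rose and 6 did not pass, with a median of -0.37 (adjusted p = 0.006; adjusted p = 0.227 with an estimated correlation). PECAM1 fell from 3.18 ± 0.37 to 0.40 ± 0.039 CPM, the angiopoietin receptor gene TEK from 35.8 ± 1.5 to 11.6 ± 0.18 CPM, RGS5 from 124 ± 4.8 to 53.5 ± 2.5 CPM and PDGFRB from 385 ± 5.4 to 298 ± 13 CPM. Except for the astrocyte list, the counts of these lists were the same adjusted over the list alone.

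Matrix and signalling lists were mixed. Of 49 extracellular matrix genes 16 rose, 26 fell and 7 did not pass (adjusted p = 0.359), of 29 TGF-beta and YAP targets 11 rose and 11 fell (adjusted p = 0.959), and of 26 Wnt pathway genes 6 rose and 13 fell (adjusted p = 0.547; 0.0402 with fry), where the median was -0.17 and the mean 0.03. Of 21 immediate early genes 13 fell, 6 rose and 2 did not pass, with a median of -0.40 (adjusted p = 0.0502); the list lay at the threshold and passed under several other settings, among them without DMSO replicate 1 (0.0456) or MRTX1719 replicate 1 (0.0292). Of 15 BCL2 family genes 10 rose, 3 fell and 2 did not pass (adjusted p = 0.0603); the list passed without DMSO replicate 1 (0.0468), without MRTX1719 replicate 2 (0.0455) and without an expression filter (0.0287). For these 5 lists the counts adjusted over the list alone were the same.

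Of the 39 lists, 19 passed camera with a preset correlation of 0.01 and none passed with a correlation estimated from the 6 libraries, where the lowest adjusted p was 0.0747 and 8 lists had an unadjusted p under 0.05. With fry, which does not compare a list with other genes, 29 passed. Camera asks whether the genes of a list move more than other genes.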

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

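The removal of the GC and length trend and the thinning to the smallest library were chosen after the results had been seen. The counts of genes past a false discovery rate of 0.05, in total and per direction, stayed within 1.5 times their main value under every alternative run, and 8009 to 8210 of the 9083 calls were kept in the same direction with 1 library left out. DESeq2 kept 8431. The number of genes changed at least 2-fold was 765 with only genes of at least 1 CPM in at least 3 libraries, where 14515 genes were tested. The number of lists past the threshold was 0 with an estimated correlation and 29 with fry, which does not compare a list with other genes; it was 18 to 23 under the other alternatives run on the lists, which leave out DESeq2. Of 1882 values of named genes, 1874 kept their direction and their side of the threshold, 6 lost significance, all for RIOK1, and 2 gained it without the trend, CLNS1A among them; none reversed. Of 699 list values 646 were the same, 26 lost significance and 27 gained it, and none reversed. The list of Sm, LSm and SMN complex genes also lost its call under upper-quartile scaling (adjusted p = 0.0508), limma-voom (0.0717), the stricter filter (0.0775) and thinning (0.0557), over a range of the main and left-out values up to 0.085 with the preset correlation. The immediate early list, at 0.0502, passed with RLE scaling (0.0469), upper-quartile scaling (0.0418), limma-voom (0.0301), no filter (0.00819), the replicate number as a block (0.039), the trend removed (0.0343) and fry (1.14e-05), and without DMSO replicate 1 (0.0456) or MRTX1719 replicate 1 (0.0292).

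Deviations of same-numbered samples from their group means correlated at 0.147, 0.074 and -0.105, and 1 of the 3 treated samples correlated best with its own number. These values show no clear pairing by number, but 3 samples per group are too few to exclude one. With the replicate number as a block 9102 genes passed. Thinning to the smallest library left 8991 calls. In the simulation, where far fewer genes were changed than passed in the real data, 42% of genes changed 1.2-fold were recovered. Genes with few counts, such as MTAP, were not tested.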

Other observations

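The genes and groups of this and the next paragraph, and the tests of GC content and length, depth, tail-less RNA and S phase, were chosen after the results were seen, while those of a block drift in ribosomal protein genes, summed histone reads, intron number and splits of the libraries were set before. All 4 measured pregnancy-specific glycoprotein genes rose, on chromosome 19 between 42866464 and 43269530. PSG4 reached 166 ± 4.4 CPM, PSG5 rose from 2.40 ± 0.19 to 8.27 ± 0.5 CPM, PSG1 from 0.38 ± 0.031 to 1.76 ± 0.19 CPM and PSG9 from 0.48 ± 0.096 to 1.72 ± 0.11 CPM (n = 3 per group), while CEACAM1, a related gene nearby, rose less, by a log2 fold change of 0.57. These copies are near-identical, so the smaller values can hold reads of PSG4. Within the BCL2 family the pro-apoptotic genes moved apart. BCL2L11, which encodes BIM, fell from 68.4 ± 1.6 to 23.3 ± 0.95 CPM and BMF from 15.4 ± 0.97 to 5.45 ± 0.057 CPM, while the p53 targets BBC3 and BAX rose 1.86-fold and 1.91-fold and HRK rose 8.36-fold from 0.42 ± 0.11 CPM. The death receptor gene FAS rose 4.71-fold and the stress cytokine gene GDF15 4.16-fold to 301 ± 5.1 CPM, and NES, which encodes nestin, fell from 418 ± 31 to 169 ± 4.7 CPM.

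Of 26 host genes of small nucleolar RNAs 13 rose, 3 fell and 10 did not pass. DANCR rose from 21.2 ± 1.1 to 46.7 ± 3 CPM, SNHG19 from 10.3 ± 0.54 to 25.7 ± 2.1 CPM, SNHG3 from 18 ± 0.67 to 35 ± 2.9 CPM and SNHG29 from 96.9 ± 3.8 to 152 ± 0.4 CPM. Because DANCR, SNHG19 and SNHG3 had drawn attention to the group, the hypothesis that these transcripts rise together was tested on the other 23, of which 10 rose and 3 fell and whose median log2 fold change of 0.211 stood at percentile 99.7 of 10000 random lists matched on mean expression. Matched on exon length as well it stood at percentile 99.3. With the GC and length trend removed the median was 0.192, at percentile 99.5 of lists matched on mean expression. The random lists were not matched on gene type, so these percentiles cannot separate the host genes from non-coding genes in general. Of 21 genes that ERK signalling is known to induce, feedback regulators among them, 14 fell and 5 rose. EGR1 fell from 35.7 ± 3.6 to 12.8 ± 0.51 CPM, ERRFI1 from 321 ± 12 to 138 ± 3.1 CPM and SPRY4 from 18.8 ± 1.3 to 8.7 ± 0.92 CPM. The 5 that rose were CCND1, FOSL1, MYC, EPHA2 and DUSP4. Without EGR1, ERRFI1 and SPRY4, which were seen first, 11 of the other 18 fell and 5 rose. Their median was -0.253, at percentile 0.34 of random lists matched on mean expression and at 0.21 with exon length matched as well. With the trend removed the median was -0.24, at percentile 0.56. Of the 21 genes 5 are also in the immediate early list, and CCND1 and MYC were in the G1/S and MYC lists. The other 18 are therefore not an independent test, and lower ERK output remains a hypothesis. A percentile among genes describes these libraries and is not a replicate test.

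One hypothesis was that genes with many introns fall when PRMT5 is inhibited, since PRMT5 acts on spliceosomal proteins. Among protein-coding genes with at least 1 CPM outside the cell cycle, replication and repair lists, 1805 genes with 20 or more introns had a median log2 fold change of -0.038 and 1322 genes with 2 or fewer had -0.017, a difference of -0.021. With the genes divided by exon length into 5 groups of equal size, the difference was 0.026, 0.087, 0.13 and 0.009 in the 4 groups of longer genes. None of these lay in the direction of the hypothesis. The last and smallest value covered 1004 of the genes with many introns, and the group of the shortest held only 1 such gene. Outside the lists left out, the gene-level counts thus show no consistent fall of genes with many introns. They say nothing of the genes in those lists or of intron retention within transcripts.

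The number of genes past the threshold, 9083, is large. With the trend of each library on GC content and exon length removed, 9192 genes passed, 8273 of them with the same direction as before. This argues against that trend as the whole cause. With all libraries thinned to the smallest total 8991 passed. The totals were similar and already scaled for in the main test, so thinning could show little about depth. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real one, and the highest other split gave 0, in total, per direction and at 2-fold. For lists the real split gave 19 and the highest other 17. Each other split sets 2 libraries of one treatment and 1 of the other against the reverse. It thus keeps part of the treatment difference and adds the rest to the spread within its sides, so its counts are not chance counts. The splits are also too few for a share under 0.05.

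The rise of cytosolic ribosomal protein genes was small, and fold changes declined with exon length over all genes, which could raise short genes. With the GC and length trend removed the median of the list was 0.185, with quartiles of 0.099 and 0.257, against 0.205 before, so this trend may account for a small part of the rise and not the whole. The mean log2 CPM of the list differed by 0.203 between groups, with a within-group range of at most 0.113 and no overlap. Chance gives such a separation of 3 from 3 in 10% of cases, and a drift that coincides with the groups would give the same values. A drift of the libraries as a block therefore cannot be told apart from an effect of the treatment. Reads of processed pseudogenes were not tested, and an effect of the treatment remains a hypothesis.

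Replication-dependent histone RNA rose while DNA replication genes fell. With unchanged RNA levels per cell in S phase, more such cells would raise the replication genes. Even the upper quartile of their log2 fold changes was -0.356. Neither their RNA per cell nor the share of cells in S phase was measured, so more cells in S phase cannot be excluded. The summed level of 49 listed histone genes rose from 235 ± 14 to 331.7 ± 5.6 CPM, a log2 ratio of 0.497. Reads moved between listed near-identical copies would leave this sum unchanged if reads that fit several places were all counted. Their treatment is not given, so the sum argues against such a shift only under that condition. More carry-over of RNA without a poly(A) tail cannot be told apart from a change in histone RNA. Only 5 small RNA genes of at least 1 CPM were measured, with a median of 0.152 and an interval from -0.559 to 1.375. Of these, Metazoa_SRP rose by a log2 fold change of 1.37 (edgeR adjusted p = 2.25e-07) and RN7SL2 by 0.51 (adjusted p = 4.71e-05). The others did not pass. The share of mitochondrial ribosomal RNA was lower in treated libraries, 0.71% to 0.75% of the counts against 0.78% to 0.89%, but this may reflect its own level. Whether this RNA lacked a tail was not tested either, so its share decides nothing about carry-over. Whether more histone transcripts carried a tail in treated cells is a further possible explanation that these counts do not test.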
